A study of Mus musculus with 9 samples.

How the data were processed

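RNA sequencing was made from regulatory T cells (Tregs) sorted as CD4+ GFP+ cells from Lewis lung carcinoma (LLC) tumours of C57BL/6 mice. The labels give 9 pools in 3 groups, with 3 pools per group and 3 to 4 mice per pool. Mock pools came from mock-transfected LLC tumours of mice labelled untreated, and both other groups came from LLC tumours expressing the integrin subunit β8, treated with an isotype control antibody or with an anti-β8 antibody (clone C6D4). Per the labels' protocols, anti-β8 was injected at 7 mg/kg 2 times a week from day 7 after tumour inoculation and tumours were taken on day 14. RNA was isolated with the RNeasy Mini kit, converted to full-length cDNA with the SMART-Seq v4 Ultra kit and made into libraries with Nextera XT, a protocol without molecular identifiers and without strand marking. The labels do not describe the GFP reporter, the numbers of cells or the library batches.

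The deposited tables hold FPKM (fragments per kilobase of transcript, scaled to library size), per the sheet names, once unnormalized with 53251 genes and once normalized with 16409 genes. The submitters' processing notes name Trim Galore 0.5.0, STAR 2.6.1a, RSEM 1.3.1, Picard, Cufflinks and the mouse build GRCm38, without saying which tool gave the values. The annotation release is not given in the sources used here, and 99.8% of the gene identifiers were found in GENCODE mouse release 21 (M21, GRCm38), from which coordinates, transcript lengths and 26 symbols that had been turned into dates were taken. The values of the normalized table show how the authors made it: it holds the genes whose highest FPKM is above 1, and the highest sorted values of the 9 libraries differ by at most 0.0907%, which is quantile normalization. Genes at 0 were averaged in that step, so anti-β8 pools 2 and 3 hold no 0 in the normalized table, with lowest values of 0.0520 and 0.0936 FPKM. From the unnormalized values 1 row whose cells were shifted was left out, and 112 identifiers repeat the symbol of another one. FPKM are not counts, so no count model was fitted.

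Before the data were examined, the groups, tests, gene lists, rule for named genes and most alternatives were fixed, and the normalized table was set as the main one provided it held at least 80% of the genes kept from the other table (it held 12767 of 12767). Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were kept, which left 12555. Values were analysed as log2(FPKM + 1), and a log2 difference is on that scale, which understates changes of genes with low values. The 3 comparisons were taken from 1 linear model of the group means of all 9 libraries in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation with trend and robust settings, a two-sided test, and Benjamini-Hochberg adjustment over the genes with a threshold of 0.05. Errors of log2 differences are standard errors (SE) of that model, and errors of FPKM are standard deviations (SD) over 3 pools. The p-values measure the spread between pools of mice, and the 9 libraries share 1 estimate of it per gene. A set of 37 gene lists (Treg, helper T cell, cytokine response, metabolism, stress, cell type marker and RNA quality genes) was tested with camera in limma at a preset inter-gene correlation of 0.01, with adjustment over the 33 lists that had at least 5 measured members, and again with an estimated correlation. Members were also adjusted over the list alone.

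The genes named were, per comparison, up to 10 with the largest rise and up to 10 with the largest fall among genes past the threshold whose pools did not overlap between groups, leaving out unnamed or predicted genes, pseudogenes and receptor segments, or, where fewer than 10 genes passed, also the 5 with the smallest p in each direction as genes that did not pass. Foxp3, Itgb8, Itgav, Lrrc32, Tgfb1, Itgae, Ctla4, Il2ra, Ikzf2 and Il10 were named in every comparison, and each list described is shown with the members of smallest p. Near-identical genes such as Hspa1a and Hspa1b, Apol9b and its neighbour Apol9a, Ly6a and other Ly6 genes, and the globin genes can share reads, and so can snoRNA or miRNA genes inside host genes, so their values are uncertain.

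Read totals are not in the tables. From the lowest values above 0 in genes with 1 transcript, the depth relative to Mock pool 1 was estimated at 1.00 to 1.29 over the 9 libraries. The numbers 1 to 3 carried by the pools are shared by the groups but did not pair them, so no block was used in the main model. Data were simulated with 1 spread per gene shared by all groups, in 5 simulations per comparison. In each, 200 of the 12555 genes were changed, all drawn from those with a mean log2 value above 3. The model recovered 24.8% of changes of log2 1 and 71.8% of changes of log2 2 for β8 isotype against Mock. It recovered 21.4% and 73.6% for anti-β8 against β8 isotype, and 22.6% and 69.8% for anti-β8 against Mock. False calls made up 4.55%, 6.50% and 4.35% of the calls in those comparisons. These shares do not cover the wider spread of the anti-β8 pools, and the recovery does not cover genes of lower values. The alternatives were the unnormalized table, 2 other scalings, 2 other pseudocounts, 2 other filters, a replicate block, fits of only the groups compared, other variance settings, array weights and leaving out each pool. Leaving out anti-β8 pools 2 and 3 together and leaving out genes shorter than 0.3 kb were added after seeing the data. Figures were drawn with matplotlib.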

Results

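The integrin αvβ8 binds latent TGF-β and releases the active cytokine, and the study asked how β8 on tumour cells acts on the Tregs inside the tumour. Gene expression was measured in 9 pools of Tregs from LLC tumours, a mouse lung carcinoma line grown in mice: 3 pools from mock-transfected tumours (Mock), 3 from β8-expressing tumours of mice given an isotype antibody (β8 isotype) and 3 from β8-expressing tumours of mice given anti-β8. Foxp3, the transcription factor that defines Tregs, was present in every group at 101 ± 15.0 FPKM in Mock, 95.3 ± 20.1 in β8 isotype and 124 ± 6.73 in anti-β8 (SD, n = 3 pools). Because the Mock mice were untreated, β8 on the tumour goes together with the isotype antibody in β8 isotype against Mock, and with the anti-β8 antibody in anti-β8 against Mock.

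Between 11785 and 12177 genes reached 1 FPKM in 7 of the libraries, but 9772 did in anti-β8 pool 2 and 9283 in anti-β8 pool 3. These pools correlated with the other 7 libraries at 0.822 to 0.856 and with each other at 0.791 (Pearson's r across genes of log2 values), the lowest of all pairs, against 0.908 to 0.946 among the other 7. The mean SD within a group was 0.96 log2 units in anti-β8, 0.61 in Mock and 0.53 in β8 isotype. Mitochondrial transcripts made up 1.27% and 1.53% of the FPKM in anti-β8 pools 2 and 3 and 0.776% to 1.16% in the other libraries.

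**Figure D1:**
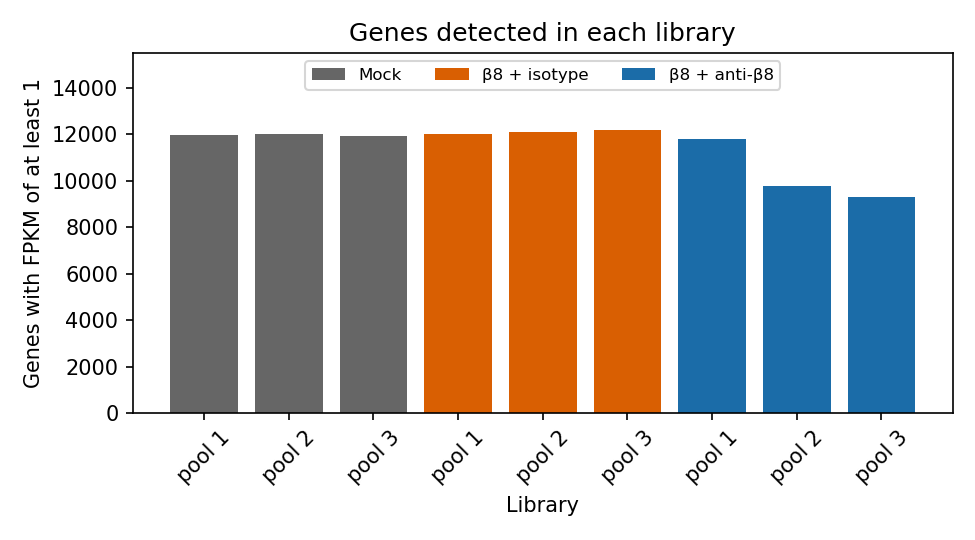
Number of genes with an unnormalized FPKM of at least 1 (y axis) in each library (x axis), coloured by group, with 1 bar per pool. Anti-β8 pools 2 and 3 stand at 9772 and 9283 genes, below the 11785 to 12177 of the other 7 libraries.

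The first comparison, β8 isotype against Mock, asked how Tregs of β8-expressing tumours differ from those of mock-transfected tumours. Ly6a, which encodes the surface protein Sca-1, rose from 345 ± 58.3 FPKM in Mock to 998 ± 44.99 in β8 isotype (log2 difference 1.54 ± 0.14 SE, n = 3 pools per group, limma adjusted p = 0.00301). Genes induced by type I interferon rose as a group: 27 of 29 measured members lay above 0, with a median log2 difference of 0.88 (camera adjusted p = 3.86e-20, and adjusted p = 0.00639 with an estimated correlation). Of these members 14 were higher when adjusted over the list alone and 0 when adjusted over all genes. They included Bst2, the antiviral protein tetherin (0.86 ± 0.13), Ifit3 (1.71 ± 0.37) and the transcription factor Irf7 (1.201 ± 0.29). Ly6a, at chromosome 15, 74994877 to 74998031 of GRCm38, was higher in 3 of 3 β8 isotype pools than in every Mock pool and was the 1 gene of 12555 that passed.

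Further immune gene lists rose with a preset correlation but not with an estimated one. The interferon-γ list (type II interferon) had a median log2 difference of 0.74 (camera adjusted p = 7.27e-14, and adjusted p = 0.114 with an estimated correlation). Of its 23 members 12 were higher adjusted over the list alone and 0 over all genes, led by the peptide transporter Tap1 (1.12 ± 0.21), the immunoproteasome subunit Psmb8 (0.68 ± 0.15) and the GTPase Igtp (0.84 ± 0.19). The Th1 and cytotoxic list had 4 of 20 members higher adjusted over the list alone and 0 over all genes (adjusted p = 0.00258, and adjusted p = 0.362 with an estimated correlation). Its members granzyme B (Gzmb) measured 472 ± 27.1 FPKM in Mock and 1039 ± 314 in β8 isotype, and granzyme C (Gzmc) 15.9 ± 9.29 and 49.8 ± 18.7. The Treg identity list had 3 of 21 members higher adjusted over the list alone, and the checkpoint and costimulation list 5 of 19, with 0 over all genes in either (adjusted p = 0.000412 for both, and adjusted p = 0.218 with an estimated correlation for both). The members of smallest p in both were the costimulatory receptors Tnfrsf4, which encodes OX40 (0.60 ± 0.12), and Tnfrsf18, which encodes GITR (0.43 ± 0.10), and the inhibitory receptor Ctla4 (0.68 ± 0.17).

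Cell cycle genes rose together, with 30 of 32 members above 0 and a median log2 difference of 1.06 (adjusted p = 1.16e-15, and adjusted p = 0.213 with an estimated correlation). Of these, 10 were higher adjusted over the list alone and 0 over all genes. Stmn1, a microtubule regulator, differed by 1.11 ± 0.28 and the replication licensing genes Mcm2 and Mcm3 by 1.18 ± 0.31 and 0.89 ± 0.25. Glycolysis genes had 5 of 17 members higher adjusted over the list alone and 0 over all genes (adjusted p = 0.000174, and adjusted p = 0.114 with an estimated correlation). Among them were Eno1 (0.52 ± 0.11), Tpi1 (0.44 ± 0.13) and Ldha (0.55 ± 0.16). The unfolded protein response list had 1 of 20 members higher adjusted over the list alone, Pdia6 (0.79 ± 0.20), and 0 over all genes. It rose with adjusted p = 0.0212, and adjusted p = 0.362 with an estimated correlation. The cholesterol synthesis list rose with 0 of 23 members past either adjustment (adjusted p = 0.0379, and adjusted p = 0.339 with an estimated correlation). Ribosomal protein genes fell, with 33 of 33 members below 0 (median -0.25, adjusted p = 7.60e-08, and adjusted p = 0.218 with an estimated correlation). Of these, 6 were lower adjusted over the list alone and 0 over all genes, such as Rps14 (-0.45 ± 0.095) and Rps27 (-0.45 ± 0.10).

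Markers of other cell types moved with the same contrast. Fibroblast markers rose (3 of 7 higher adjusted over the list alone and 0 over all genes, adjusted p = 1.68e-06, and adjusted p = 0.213 with an estimated correlation). The matrix proteoglycan decorin (Dcn) measured 3.30 ± 2.40 FPKM in Mock and 55.3 ± 28.6 in β8 isotype, and the collagen gene Col3a1 3.17 ± 0.787 and 42.8 ± 23.3. B and plasma cell markers rose with 0 of 12 members past either adjustment (adjusted p = 0.000715, and adjusted p = 0.362 with an estimated correlation), with Cd79b at 1.17 ± 0.49. Tumour and epithelial markers rose with 1 of 11 members higher adjusted over the list alone and 0 over all genes, the matrix protein Cyr61 at 3.35 ± 0.82 (adjusted p = 0.00101, and adjusted p = 0.218 with an estimated correlation). Erythroid and platelet markers fell with 1 of 5 members lower adjusted over the list alone and 0 over all genes, the globin Hbb-bt at -3.44 ± 0.83 (adjusted p = 0.000715, and adjusted p = 0.362 with an estimated correlation).

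Besides those above, the genes of smallest p that did not pass included lactoferrin (Ltf), at 12.6 ± 2.01 FPKM in Mock and 64.4 ± 21.6 in β8 isotype, and the protease inhibitor Ctla2a, at 606 ± 43.0 and 318 ± 31.5. Others were Tmem158, at 313 ± 42.6 and 159 ± 8.52, the trefoil peptide Tff1, at 242 ± 69.1 and 91.6 ± 18.7, and Emb, at 230.4 ± 18.6 and 143 ± 11.5. The genes of the αvβ8 and TGF-β axis did not pass. The log2 difference was -0.055 ± 0.41 for Itgb8, -0.057 ± 0.19 for Itgav and 0.34 ± 0.39 for Lrrc32, which encodes the latent TGF-β carrier GARP. It was 0.21 ± 0.24 for Tgfb1 and 0.048 ± 0.56 for the TGF-β-induced integrin gene Itgae. Foxp3 differed by -0.094 ± 0.20, the IL-2 receptor Il2ra by 0.22 ± 0.20, the Treg transcription factor Ikzf2 by 0.88 ± 0.40 and the cytokine gene Il10 by 0.49 ± 0.49. The TGF-β response list did not pass (median -0.086, 0 of 22 members past either adjustment, adjusted p = 0.292). At an unadjusted p under 0.05 there were 375 higher and 324 lower genes, 699 in all. By chance 628 would be expected with equal spread in all groups. Groups simulated without change at the spread of each group gave a mean of 223. The 699 became 1525 with only the 6 libraries of these groups and 1610 with array weights. The pools of the groups did not overlap in 17.5% of genes, where chance gives 10% for groups of equal spread. With only the 6 libraries of these groups 29 genes passed (18 higher and 11 lower). With a replicate block 2 passed, with array weights 111 and without trend and robust settings 0. Leaving out Mock pool 1, β8 isotype pool 3, anti-β8 pool 1 or anti-β8 pool 2 gave 2 genes.

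**Figure D2:**
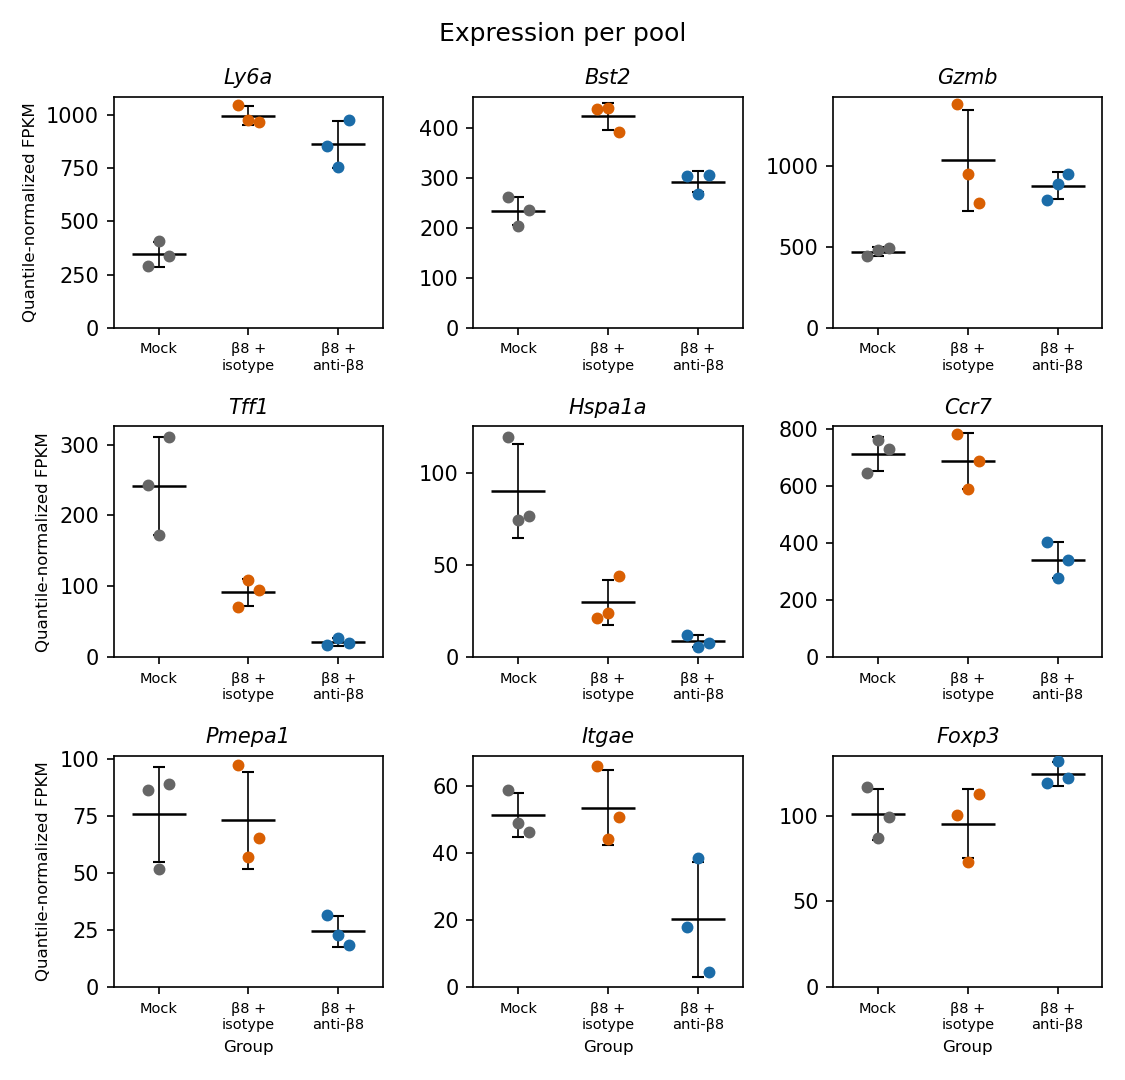
Quantile-normalized FPKM (y axis, linear, from 0) of 9 genes in each group (x axis), with 1 point per pool, a line at the mean and error bars of 1 SD over 3 pools. Ly6a stands at a mean of 345 FPKM in Mock, 998 in β8 isotype and 863 in anti-β8, while Tff1 stands at 242, 91.6 and 22.04.

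The next comparison, anti-β8 against β8 isotype, asked what blocking β8 changed in Tregs of β8-expressing tumours. Nfkbia, the inhibitor of NF-κB, fell from 2033 ± 103 FPKM in β8 isotype to 1323 ± 121 in anti-β8 (log2 difference -0.62 ± 0.087 SE, n = 3 pools per group, limma adjusted p = 0.0408). Tff1 fell from 91.6 ± 18.7 to 22.04 ± 5.48 FPKM (-2.01 ± 0.27, adjusted p = 0.0408), the apolipoprotein L gene Apol9b from 17.7 ± 1.66 to 1.61 ± 1.31 (-3.01 ± 0.45, adjusted p = 0.0497) and the myelin-associated gene Ncmap from 92.2 ± 15.3 to 19.2 ± 10.5 (-2.31 ± 0.32, adjusted p = 0.0408). The TGF-β response list fell, with 18 of 22 members below 0 and a median log2 difference of -0.43 (camera adjusted p = 0.00139, and adjusted p = 0.409 with an estimated correlation). Over the alternatives the list's median ranged from -0.59 to -0.21. Of its members 6 were lower adjusted over the list alone and 0 over all genes. These were the transcriptional regulator Id2 (-0.63 ± 0.12), the TGF-β target Pmepa1 (-1.54 ± 0.30), Rgs16 (-0.72 ± 0.21), the SMAD corepressor Ski (-1.33 ± 0.39), the ectoenzyme Nt5e, or CD73 (-2.01 ± 0.62), and Itgae, or CD103 (-1.75 ± 0.56). Itgae differed by -0.98 without anti-β8 pool 3 and by -2.41 without pool 2.

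The Treg identity list fell with 4 of 21 members lower adjusted over the list alone and 0 over all genes (adjusted p = 0.00139, and adjusted p = 0.409 with an estimated correlation). Nt5e and Itgae are also members of the TGF-β response list, so the falls of these lists are not independent. Il10 measured 59.1 ± 18.3 FPKM in β8 isotype and 17.0 ± 12.1 in anti-β8, Ikzf2 102 ± 12.5 and 42.1 ± 31.5, Nt5e 23.4 ± 7.08 and 7.12 ± 6.87, and Itgae 53.6 ± 11.2 and 20.3 ± 17.1. With anti-β8 pool 1 as the only anti-β8 library the log2 difference was -0.38 for Ikzf2 and -0.93 for Il10, in place of -1.50 and -1.96, so the size of both falls rested in large part on the pools of low detection. Foxp3, a member of the Treg identity list, lay in the other direction at 0.40 ± 0.20 (adjusted p = 0.509). Chemokine receptor and homing genes fell with 8 of 26 members lower adjusted over the list alone and 0 over all genes (adjusted p = 0.00281, and adjusted p = 0.409 with an estimated correlation). The lymph node homing receptor Ccr7 measured 689 ± 96.8 and 342 ± 62.7 FPKM (-1.02 ± 0.15, adjusted p = 0.0543). The gut homing receptor Gpr15 measured 3.80 ± 0.682 and 0.311 ± 0.412, and the selectin ligand enzyme Fut7 10.2 ± 3.79 and 1.18 ± 1.92. Checkpoint and costimulation genes fell with 5 of 19 members lower adjusted over the list alone and 0 over all genes (adjusted p = 0.00139, and adjusted p = 0.409 with an estimated correlation). Among them were Pdcd1, or PD-1 (-0.90 ± 0.24), Icos (-0.77 ± 0.21) and Ctla4 (-0.50 ± 0.17). Cell cycle genes fell with 1 of 32 members lower adjusted over the list alone, the spindle checkpoint kinase Bub1b (-2.32 ± 0.50), and 0 over all genes (adjusted p = 0.00139, and adjusted p = 0.415 with an estimated correlation). Type I interferon genes fell with 3 of 29 lower adjusted over the list alone, among them Oasl2 (-2.63 ± 0.65) and Bst2 (-0.53 ± 0.13), and 0 over all genes (adjusted p = 0.0415, and adjusted p = 0.409 with an estimated correlation). In anti-β8 the SD exceeded the mean for Gpr15, Fut7, Bub1b (0.338 ± 0.460 FPKM) and Oasl2 (1.40 ± 2.31). Their values there were low, so the size of these 4 falls may rest on the pools of low detection.

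Genes induced by tissue dissociation fell with 6 of 23 members lower adjusted over the list alone and 0 over all genes (adjusted p = 0.00137, and adjusted p = 0.409 with an estimated correlation). They were led by the heat shock genes Hspa1a (-1.65 ± 0.36) and Hspa1b (-1.59 ± 0.36) and by Jun (-0.75 ± 0.18). The list of mitochondrially encoded transcripts rose, with 12 of 12 members above 0 (median 0.65, adjusted p = 1.03e-06, and adjusted p = 0.409 with an estimated correlation). Of these, 4 were higher adjusted over the list alone and 1 over all genes, mt-Atp8, with mt-Nd2 at 0.66 ± 0.19. Without anti-β8 pools 2 and 3 the median was 0.11, at percentile 79.4 of matched random lists, so the size of this rise rested on those pools. Ribosomal protein genes rose with 0 of 33 members past either adjustment, Rps7 at 0.38 ± 0.10 (adjusted p = 0.00281, and adjusted p = 0.409 with an estimated correlation). B and plasma cell markers rose with 0 of 12 members past either adjustment, Cd22 at 2.04 ± 0.58 (adjusted p = 0.0110, and adjusted p = 0.409 with an estimated correlation). Fibroblast markers fell with 1 of 7 lower adjusted over the list alone and 0 over all genes, Lum at -2.35 ± 0.50 (adjusted p = 0.0490, and adjusted p = 0.409 with an estimated correlation). Tumour and epithelial markers fell with 1 of 11 lower adjusted over the list alone and 0 over all genes, Areg at -1.46 ± 0.27 (adjusted p = 0.0281, and adjusted p = 0.409 with an estimated correlation). Areg, amphiregulin, is also made by Tregs.

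In all, 1 gene was higher and 7 were lower of 12555. The genes that passed besides Nfkbia, Tff1, Apol9b and Ncmap are short. The small nucleolar RNA Snord83b (94 nt, chromosome 15, 80078498 to 80078591 of GRCm38, inside Rpl3) and the microRNA gene Mir1938 (100 nt, chromosome 12, 40222712 to 40222811, inside Ifrd1) were listed at 0 in the 3 anti-β8 pools of the unnormalized table. They stood at 18.5 to 85.6 and 19.3 to 37.5 FPKM in the other 6 libraries (adjusted p = 0.00121 for both). FPKM are scaled to transcript length, so at 94 and 100 nt a few reads can give such values. Those of Mir1938 were 19.3, 20.7 and 37.5 in Mock and 35.8, 22.7 and 19.7 in β8 isotype. Read counts are not known, so whether the calls of Snord83b and Mir1938 rest on few reads cannot be told. The predicted snRNA gene Gm25313 (116 nt) was listed at 0 in the 3 anti-β8 pools and at 9.39 to 52.1 FPKM elsewhere (adjusted p = 0.0408). It falls outside the rule for named genes and was chosen after its values were seen. mt-Atp8 (204 nt) was listed at 0 in the 6 other libraries and at 4.27, 2.34 and 2.78 FPKM in the anti-β8 pools (adjusted p = 0.0497). Of the genes fixed for every comparison not yet given, Itgav differed by -0.78 ± 0.19, Itgb8 by -0.51 ± 0.41, Lrrc32 by -0.82 ± 0.39, Tgfb1 by -0.41 ± 0.24 and Il2ra by -0.29 ± 0.20, and none passed.

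The genes of smallest p that did not pass, besides Ccr7, included the monocyte chemokine Ccl7 (-3.09 ± 0.52), the nuclear envelope gene Tmpo (-1.001 ± 0.17), Gzmc (-2.40 ± 0.42) and Ctla2a (-0.83 ± 0.15) among lower values. Among higher ones they included the neuropeptide receptor Nmur1 (2.67 ± 0.61), Snora57 (1.27 ± 0.30), the glycolytic gene Gapdh (0.47 ± 0.12) and Atrn (2.23 ± 0.57). At an unadjusted p under 0.05 there were 499 higher and 778 lower genes, 1277 in all. By chance 628 would be expected with equal spread in all groups. Groups simulated without change at the spread of each group gave a mean of 850. The 1277 became 944 with only the 6 libraries of these groups, 628 without both anti-β8 pools of low detection and 687 with array weights. Without both pools 1 anti-β8 library is left, so that the spread comes from the other groups alone. Pools did not overlap in 15.0% of genes. Chance gives 10% for groups of equal spread, which these were not (mean SD 0.96 log2 units in anti-β8 and 0.53 in β8 isotype). The count moved from 8 to 142 without anti-β8 pool 1 and to 12 without both anti-β8 pools of low detection (1 anti-β8 library left), and to 2 to 5 without any other single pool. It was 2 with the unnormalized table (0 higher and 2 lower) or with median-of-ratios scaling, 3 with only the 6 libraries of these groups. Without genes shorter than 0.3 kb it was 0, so that Nfkbia, Tff1, Apol9b and Ncmap were no longer past the threshold.

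The third comparison, anti-β8 against Mock, asked how far Tregs of treated β8-expressing tumours lay from those of mock-transfected tumours. Ly6a rose from 345 ± 58.3 FPKM in Mock to 863 ± 109 in anti-β8 (log2 difference 1.33 ± 0.14 SE, n = 3 pools per group, limma adjusted p = 0.00229). The proteasome activator Psme2 rose from 478 ± 22.6 to 776 ± 79.7 (0.69 ± 0.11, adjusted p = 0.0389) and the cytokine Mif from 914 ± 73.2 to 1410 ± 107 (0.63 ± 0.10, adjusted p = 0.0399). Tff1 fell from 242 ± 69.1 to 22.04 ± 5.48 FPKM (-3.38 ± 0.27, adjusted p = 0.000419). The inducible heat shock genes Hspa1a and Hspa1b fell from 90.5 ± 25.5 to 8.75 ± 3.29 (-3.25 ± 0.36, adjusted p = 0.00333) and from 106 ± 11.7 to 10.4 ± 2.98 (-3.26 ± 0.36, adjusted p = 0.00352). The TGF-β response list fell, with 17 of 22 members below 0 and a median of -0.63 (camera adjusted p = 0.000175, and adjusted p = 0.340 with an estimated correlation). Of these, 10 were lower adjusted over the list alone and 0 over all genes. Those of smallest p were Pmepa1, at 75.7 ± 20.8 FPKM in Mock and 24.4 ± 6.67 in anti-β8, Rgs16, at 278 ± 15.5 and 137 ± 14.6, and Id2, at 1397 ± 51.9 and 952 ± 136.

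Of 12555 genes, 4 were higher and 19 lower. Besides those above, Apol9b (-3.86 ± 0.45, adjusted p = 0.00439), the neuropeptide gene Calca (-2.96 ± 0.48, adjusted p = 0.0399), the myosin phosphatase gene Ppp1r12b (-2.53 ± 0.41, adjusted p = 0.0399), and Ncmap (-2.13 ± 0.32, adjusted p = 0.0319) were lower in anti-β8. So were Ctla2a (-1.76 ± 0.15, adjusted p = 0.000541), Tmem158 (-1.62 ± 0.16, adjusted p = 0.00204), Ccr7 (-1.07 ± 0.15, adjusted p = 0.0252) and the scavenger receptor Stab1 (-2.10 ± 0.34, adjusted p = 0.0432). The transcription factor Ovol2 was listed at 0 in the 3 anti-β8 pools and averaged 5.90 FPKM in Mock (adjusted p = 0.0350). Snord83b and Mir1938 were listed at 0 in anti-β8 and mt-Atp8 at 0 in Mock (adjusted p = 0.000295, 0.000556 and 0.0253), and the other lower genes were the small nucleolar RNA gene Snord118 and 4 unnamed or predicted genes.

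Genes induced by type I interferon rose against Mock in this group too, with 26 of 29 members above 0, 6 higher adjusted over the list alone and 0 over all genes (adjusted p = 6.85e-06, and adjusted p = 0.127 with an estimated correlation). Among them were Parp14 (1.86 ± 0.35), Ifit1 (1.55 ± 0.33) and Zbp1 (1.17 ± 0.25). The type II list had 6 of 23 members higher adjusted over the list alone and 0 over all genes, such as the GTPases Gbp2 (1.48 ± 0.29) and Igtp (0.91 ± 0.19) (adjusted p = 3.19e-05, and adjusted p = 0.340 with an estimated correlation). Glycolysis genes rose with 9 of 17 members higher adjusted over the list alone and 0 over all genes, led by Gapdh (0.66 ± 0.12) and Eno1 (0.51 ± 0.11) (adjusted p = 4.67e-05, and adjusted p = 0.127 with an estimated correlation). Cell cycle genes rose with 4 of 32 higher adjusted over the list alone and 0 over all genes, among them Mcm3 (1.04 ± 0.25), Mcm2 (1.14 ± 0.31) and Mcm4 (1.15 ± 0.32) (adjusted p = 0.0175, and adjusted p = 0.758 with an estimated correlation). The Th17 list fell with 2 of 9 lower adjusted over the list alone, the chemokine receptor Ccr6 (-1.58 ± 0.37) and the nuclear receptor Rora (-0.42 ± 0.14), and 0 over all genes (adjusted p = 0.0140, and adjusted p = 0.340 with an estimated correlation).

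Dissociation-induced genes fell with 10 of 23 members lower adjusted over the list alone and 2 over all genes, Hspa1a and Hspa1b (adjusted p = 4.67e-05, and adjusted p = 0.260 with an estimated correlation). Mitochondrial transcripts rose with 9 of 12 higher adjusted over the list alone and 1 over all genes (adjusted p = 1.10e-06, and adjusted p = 0.342 with an estimated correlation), with mt-Cytb at 0.56 ± 0.16. Their median of 0.69 became 0.19 without anti-β8 pools 2 and 3. B and plasma cell markers rose with 9 of 12 higher adjusted over the list alone and 0 over all genes (adjusted p = 7.97e-06, and adjusted p = 0.340 with an estimated correlation). The B cell receptor component Cd79a measured 17.0 ± 11.6 FPKM in Mock and 76.6 ± 14.5 in anti-β8. Erythroid and platelet markers fell with 3 of 5 lower adjusted over the list alone and 0 over all genes, Hbb-bs at -4.11 ± 0.78 (adjusted p = 0.0140, and adjusted p = 0.605 with an estimated correlation). Of the genes fixed for every comparison, none passed. Foxp3 differed by 0.31 ± 0.20, Itgb8 by -0.57 ± 0.41, Itgav by -0.83 ± 0.19, Lrrc32 by -0.48 ± 0.39 and Tgfb1 by -0.20 ± 0.24. Itgae differed by -1.71 ± 0.56, Ctla4 by 0.18 ± 0.17, Il2ra by -0.072 ± 0.20, Ikzf2 by -0.62 ± 0.40 and Il10 by -1.47 ± 0.49. At an unadjusted p under 0.05 there were 765 higher and 988 lower genes, 1753 in all. By chance 628 would be expected with equal spread in all groups, but anti-β8 had a wider one, for which no count was simulated here. The 1753 became 1159 with only the 6 libraries of these groups, 1108 without both anti-β8 pools of low detection (1 anti-β8 library left) and 954 with array weights. Pools did not overlap in 16.3% of genes. Chance gives 10% for groups of equal spread, which these were not (mean SD 0.96 log2 units in anti-β8 and 0.61 in Mock). The count of 23 moved to 323 without anti-β8 pool 1, 53 without anti-β8 pool 2, 9 without Mock pool 2 or 3, 11 without Mock pool 1 and 15 without β8 isotype pool 1. It was 27 without both anti-β8 pools of low detection (1 anti-β8 library left), and the unnormalized table gave 1 higher and 16 lower genes.

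**Figure D3:**
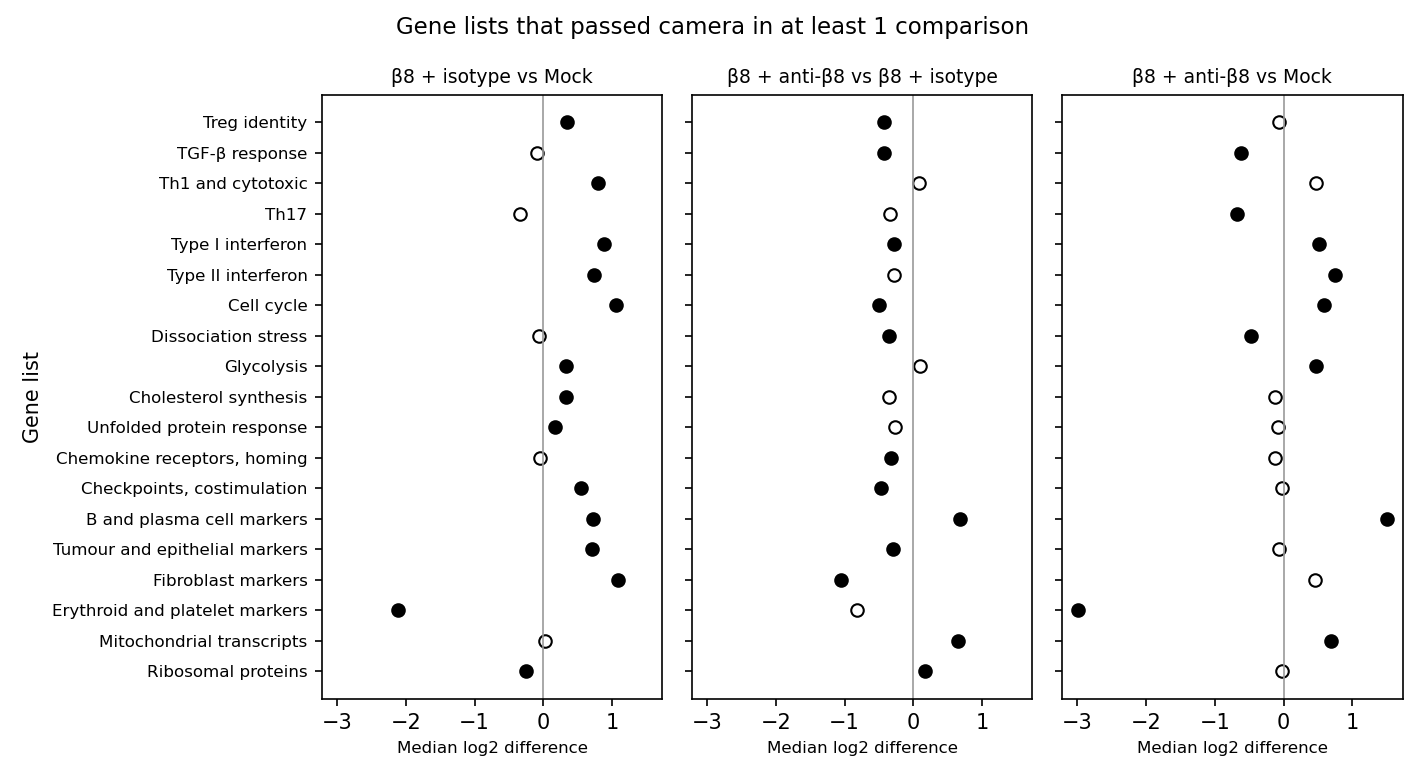
Median log2 difference over the measured members (x axis) of the 19 gene lists (y axis) that passed camera in at least 1 comparison, with 1 panel per comparison. Filled points have a camera adjusted p under 0.05 at the preset correlation and open points do not. The TGF-β response list lies at -0.086, -0.43 and -0.63, and the type I interferon list at 0.88, -0.28 and 0.52.

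Whether anti-β8 moved genes back towards Mock was read from the differences of the first 2 comparisons across genes. Bst2 measured 234 ± 28.6 FPKM in Mock, 423 ± 27.4 in β8 isotype and 292 ± 21.4 in anti-β8. Ly6a and Gzmb stood at 863 ± 109 and 879 ± 83.4 FPKM in anti-β8, against 998 ± 44.99 and 1039 ± 314 in β8 isotype. Tmem158 measured 313 ± 42.6, 159 ± 8.52 and 101 ± 15.1 FPKM in the same order of groups. Across 12555 genes, which are not independent replicates, Pearson's r between the differences was -0.29 and Spearman's rho -0.25. Both differences share the β8 isotype libraries, and groups simulated without any change gave a mean r of -0.32 (100 simulations, -0.36 to -0.26). The simulations used the spread of each group, a setting chosen after an equal spread had been tried, and the counts from them below were added after the results were seen. The covariance was -0.11, against -0.079 in the simulations and -0.093 from the spread of the β8 isotype pools. At an unadjusted p under 0.05, 97 genes were higher and then lower and 55 lower and then higher, 152 in all, which is 4.21 times the number from independent lists. The simulations without change gave 4.28 to 9.35 times that number. Their counts were 30 to 67, from fewer genes at such a p (a mean of 223 in the first comparison and 850 in the next). In the same direction there were 27 genes (35.0 from independent lists, 0 to 9 in the simulations), and 0 genes passed the adjusted threshold in opposite directions. Pearson's r was not stronger than groups without change gave, while the counts in both directions were above the simulated ones. The observed lists at such a p were longer (699 and 1277 genes) than the simulated ones. The ratio to independent lists depends on these lengths, so its place below the simulated range decides nothing about a reversal. These values do not show a reversal across genes and do not exclude one for some of them.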

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

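Leaving out anti-β8 pools 2 and 3 together and leaving out short genes were chosen after the data were seen, and the other alternatives before. Genes past the threshold in the main model kept their direction under every alternative in which they were tested, and so did the gene lists, of which 1, 0 and 0 passed with an estimated correlation (β8 isotype against Mock, anti-β8 against β8 isotype, anti-β8 against Mock). Many of the gene calls were lost, though. In anti-β8 against β8 isotype Nfkbia passed under 4 of 22 alternatives, Tff1 and Apol9b under 7, Ncmap under 6, mt-Atp8 under 3 of 20 and Gm25313 under 6 of 21, while Snord83b and Mir1938 passed under 21 of 21. In anti-β8 against Mock Ppp1r12b passed under 3 of 22, Mif under 4, Psme2 and Calca under 6, Ncmap under 11, Apol9b under 19, Ly6a and Hspa1b under 21 and Tff1 and Hspa1a under 22, and in β8 isotype against Mock Ly6a passed under 21. At the preset correlation the TGF-β response list passed under 22 of 22 alternatives in both anti-β8 comparisons. In anti-β8 against β8 isotype the type I interferon, tumour and fibroblast lists passed under 13, 16 and 10 of them. For β8 isotype against Mock the count of 1 gene became 29 with only the groups compared, 30 without both pools of low detection (nearly the same fit, since the 1 anti-β8 library left adds no spread), 111 with array weights, 0 without trend and robust settings, and 1 to 2 when 1 pool was left out. For anti-β8 against β8 isotype the count of 8 became 2 with the unnormalized table or median-of-ratios scaling, 3 with a pseudocount of 0.1 or 0.01, 3 with only the groups compared, 3 without trend and robust settings, 0 with short genes left out, and 2 to 142 when 1 pool was left out. For anti-β8 against Mock the count of 23 became 11 with a pseudocount of 0.01, 15 with no filter, 13 without trend and robust settings, 14 with array weights, and 9 to 323 when 1 pool was left out. The correlation of -0.29 between differences became -0.37 with a pseudocount of 0.01, -0.23 without both pools, and -0.40 to -0.24 when 1 pool was left out. Fitting the replicate number as a block gave 2, 2 and 15 genes, but the numbers do not pair the pools, whose deviations correlated at -0.040 to 0.046 within a number and -0.045 to 0.071 between numbers. Signs turned only for genes that did not pass. Itgb8 in β8 isotype against Mock was 0.041 with the unnormalized table, and in anti-β8 against Mock Lrrc32, Tgfb1 and Ikzf2 were 0.041, 0.11 and 0.51 without both pools. When 1 pool was left out, β8 isotype against Mock ranged from -0.22 to 0.083 for Foxp3, -0.26 to 0.15 for Itgb8, -0.16 to 0.037 for Itgav and -0.11 to 0.18 for Itgae, and anti-β8 against Mock from -0.77 to 0.071 for Lrrc32 and -0.27 to 0.046 for Il2ra. With the unnormalized table the median of all genes lay at -0.20 in anti-β8 against β8 isotype and at -0.15 in anti-β8 against Mock, and at -0.13 in both with median-of-ratios scaling. The counts with fewer pools or groups rest on fewer samples. With only the groups compared, the log2 differences of β8 isotype against Mock stay the same and only the estimate of spread changes. The rise from 1 to 29 genes therefore comes from leaving the wider anti-β8 pools out of it (mean SD 0.96 log2 units, against 0.61 in Mock and 0.53 in β8 isotype). For the other changes the cause was not tested. Read totals are unknown, so genes with low values in anti-β8 pools 2 and 3 limit what the anti-β8 comparisons can detect. The planned count model was not run because the tables hold no counts.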

Other observations

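The test on sequencing depth and the fit without both anti-β8 pools of low detection were chosen after the results were seen, and so were the reading of the test on joint zeros, the test on short RNAs with only 2 groups and the genes named in this paragraph. When Mock and β8 isotype were fitted on their own 6 libraries in limma, 29 genes passed at an adjusted p under 0.05. The 18 that rose included Irf7 (47.5 ± 8.10 FPKM in Mock and 111 ± 21.8 in β8 isotype, adjusted p = 0.0373) and Bst2 (234 ± 28.6 and 423 ± 27.4, adjusted p = 0.0226). Psmb8 (518 ± 42.2 and 829 ± 38.2, adjusted p = 0.0232), the peptide loading factor Tapbp (164 ± 27.0 and 384 ± 83.0, adjusted p = 0.0210) and the ISG15 conjugating enzyme Ube2l6 (58.7 ± 10.4 and 124 ± 17.2, adjusted p = 0.0447) rose as well. The costimulatory receptor Tnfrsf4 rose from 960 ± 127 to 1445 ± 51.2 FPKM (adjusted p = 0.0464) and the membrane protein Ms4a4b from 84.7 ± 9.20 to 211 ± 11.2 (adjusted p = 0.00467). Genes typical of other cells rose as well, Col3a1, Ltf, Ccl7, Cyr61 and the antibody heavy chain Ighg2c, while the 11 that fell included Ctla2a, Tmem158, Tff1, the keratin Krt83 (90.1 ± 18.4 and 39.8 ± 5.53 FPKM) and the globin Hbb-bt.

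Of the 33 lists tested, 14 passed in none of the comparisons, with adjusted p between 0.0559 and 0.993. These were activated tumour Treg genes, the TGF-β activation machinery, Th2 genes, naive and central memory genes, T cell receptor activation genes, hypoxia, oxidative phosphorylation and lipid uptake genes, nuclear RNAs, and markers of CD8 T cells, conventional CD4 activation, macrophages and monocytes, dendritic cells and NK cells. Some of them depended on the anti-β8 pools of low detection. With anti-β8 pool 1 as the only anti-β8 library, the medians in anti-β8 against β8 isotype moved from -0.038 to 0.56 for naive and central memory genes, from -0.24 to 0.72 for NK markers and from 0.13 to 0.38 for macrophage and monocyte markers. These are values of 1 pool. In the T cell receptor list 1 of 24 members, Nfkbia, passed over all genes in anti-β8 against β8 isotype, and in the naive and central memory list 1 of 18, Ccr7, passed in anti-β8 against Mock. Another 4 lists (neutrophil, endothelial, skin and muscle, and sex-linked genes) had fewer than 5 measured members and were not tested.

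Anti-β8 pools 2 and 3 detected fewer genes than the other 7 libraries. A lower sequencing depth is argued against by the level of the lowest values above 0, from which the depth of these pools came to 1.04 and 0.942 of the median of the other libraries. Independent loss of transcripts in each pool, as from few cells or little RNA, stays open. In all, 775 genes were at 0 in both pools, 1.66 times as many as independent losses within 50 bins of abundance would give. That is above the bound of 1.5 set beforehand, but the ratio was 1.69 to 3.83 in the 35 other pairs of libraries, so the bound does not separate the explanations. Numbers of sorted cells and library dates are not given in the labels, and a response to anti-β8 that differs between pools was not tested.

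The lower TGF-β response list in anti-β8 than in β8 isotype could come from low detection or from the antibody. Low detection in pools 2 and 3 as the whole cause was set against random lists matched on mean expression and transcript length. The list's median of -0.43 lay at percentile 0.09 of 10000 such lists (95% of them between -0.24 and 0.15), which met the bound set beforehand. Without both pools, with 1 anti-β8 pool left, it was -0.29. Some lists that camera did not call also lay low, such as type II interferon at percentile 0.84 and T cell receptor activation at 0.97, while hypoxia lay at 69.0. Random genes were drawn singly and lack the correlation of list members, so the percentile does not exclude low detection. A lower share of T cells in the pools is argued against by 10 genes of the T cell and Treg core. Their median difference, with Cd3e, Cd4, Lck and Foxp3 among them, was 0.021, and 10 of 10 lay above the median of the list. Markers of other cells did move in this comparison, B and plasma cell markers up (median 0.68) and fibroblast markers down (median -1.05). The core genes do not exclude a changed share of such cells. The camera result of the TGF-β response list was lost with an estimated correlation. Low detection, an effect of anti-β8, a difference in handling that goes with the treated group (the dissociation list also fell) and chance stay open. Heat shock genes also differed outside the treated group: Hspa1a measured 90.5 ± 25.5 FPKM in Mock and 29.9 ± 12.3 in β8 isotype. In β8 isotype against Mock the dissociation list did not pass (camera adjusted p = 0.0757). Of its members 2 were lower and 1 was higher adjusted over the list alone.

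A group of 7 genes was at 0 in all 3 anti-β8 pools and above 1 FPKM in the other 6 libraries: Snord83b, Mir1938, Gm25313, Zpbp2, Akr1b8, Dsel and Gm15530. Losses in pools 2 and 3 that coincide with a 0 in a further library may account for this number, but not with every library. With these pools, Mock pool 1 and Mock pool 3 gave 14 such genes each, and Mock pool 2 gave 1. The β8 isotype pools 1, 2 and 3 gave 2, 4 and 3, below the 7 of the real set. A difference in how short RNAs were recovered or quantified in anti-β8 libraries may account for the 3 of the 7 genes under 0.3 kb. It would not account for the other 4. In anti-β8 against β8 isotype genes under 0.3 kb had an unadjusted p under 0.05 in 15.4% of 306 cases, at percentile 99.8 of random sets of longer genes matched on expression, which met the bound set beforehand for this explanation. With only the 6 libraries of anti-β8 and β8 isotype the share was 20.6% at percentile 100 (median of the random sets 7.52%). With only those of anti-β8 and Mock it was 22.9% at percentile 100 (random median 7.84%). With only those of β8 isotype and Mock, where no anti-β8 library enters, it was 14.4% at percentile 97.3 (random median 11.1%), just under that bound. In the main model, whose spread the anti-β8 pools enter, β8 isotype against Mock gave 9.15% at percentile 99.9, above the bound, so the excess was not shown to be limited to anti-β8 libraries. Such a difference goes with the treated group, so an effect of the antibody on these RNAs stays open. The host gene Rpl3 of Snord83b differed by 0.15 ± 0.099 between anti-β8 and β8 isotype, and Ifrd1, the host of Mir1938, by -0.83 ± 0.27 (adjusted p = 0.424).

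Each comparison of 3 pools with 3 has 10 splits of its 6 libraries, too few for a share under 0.05. For β8 isotype against Mock the real split gave 1 gene and the highest other split 3, with 9 of the 10 splits giving at least 1. For anti-β8 against β8 isotype the real split gave 8 genes and the highest other 4, and for anti-β8 against Mock 23 and 3, so that 1 split of the 10, the real one, gave as many in each. For gene lists the real splits gave 14, 12 and 10 and the highest others 13, 12 and 6, with 1, 2 and 1 splits giving as many.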
